A study of Mus musculus with 21 samples.

How the data were processed

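Heart ventricle RNA of male mice aged 2 months was measured by RNA sequencing in 21 samples, with 1 library per sample in 6 groups of background and genotype. Per the labels' protocols the libraries were stranded and made from polyA RNA. The submitters' processing notes name HISAT, featureCounts, DESeq2 and the build GRCm38.p6, without versions, settings or the use of strand in counting. The deposited table holds 14732 genes by symbol, and the lowest total of a gene over all libraries is 10 reads. The authors gave raw read counts per gene and library, which were used for every test. Per the file headers, the authors also gave log2 fold changes for AJ-F1, for a pooled group and for comparisons between backgrounds. Per the file headers, adjusted p-values of the same comparisons were deposited. The deposited calls of the authors are a score of -1, 0 or 1 per gene and comparison, with a threshold that was not stated. The pooled group was identified as BL6J and CAST-F1 together by computing the same comparison again. Variance-stabilised values and z-scores in the table were not used here. No gene of the mitochondrial genome is in the table.

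Samples were grouped by the background and genotype in their labels, and the count columns were matched to them by background, genotype and replicate number. The labels name KO/Y animals and WT/Y littermates but do not say which animals shared a litter, or whether each library came from a separate animal, so the p-values measure the spread between samples. Total counts per library ran from 3848172 to 10738130, and TMM factors from 0.860 to 1.07. Of the 14732 genes, 12333 passed filterByExpr over the 6 groups and were tested, and these held 99.9% of the counts. The common biological coefficient of variation was 20.3%. Libraries of a group correlated pairwise with r of 0.895 to 0.983 over 27 pairs, and no pair was identical.

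The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those named as added in the closing section. The test was edgeR's quasi-likelihood F test with robust estimation (edgeR 4.0.16, limma 3.58.1, R 4.3.3), fitted to all 21 libraries with 6 group means, TMM normalisation and no covariates. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The contrasts were KO against WT within each background, the average of these, the pairwise differences of these, and the WT groups of AJ-F1 and CAST-F1 against that of BL6J. Log2 CPM for principal components and list tests used a prior count of 2. CPM values in the text are scaled with TMM factors. Lower counts in AJ-F1 or CAST-F1 can also arise where strain alleles align less well to the reference.

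Of 35 lists of genes, 30 had at least 3 tested members and were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a contrast. The lists cover cardiolipin synthesis and remodelling, the integrated stress response, serine, glycine, one-carbon and proline synthesis, cytosolic tRNA synthetases, mitochondrial protein quality control, endoplasmic reticulum chaperones, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, PPAR targets, glycolysis, cristae, antioxidant response, hypertrophy, mature cardiomyocyte function, extracellular matrix, interferon response, cell cycle, cholesterol synthesis, protein degradation, circadian clock, immediate early genes and markers of cell types.

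Genes were named by rule. The rule took a fixed panel of 26 genes, among them Taz, Nppa, Asns, Gdf15 and Col1a1. It took the 8 largest rises and 8 largest falls of each background among called genes with at least 5 CPM in a group and no overlap between KO and WT libraries, and up to 4 members of each described list with the smallest adjusted p. It also took the 10 genes called in all 3 backgrounds with the largest minimum change, the 8 largest differences between backgrounds with at least 5 CPM, and the 5 largest differences in each direction between controls. Not every gene that the rule names is reported here. A group at 0 reads was given a floor of 3 counts over the group, and a group of 1 to 3 reads a ratio with a 95% counting interval. Positions and biotypes are those of GRCm38, and 14435 of the symbols were found in the reference, of which 14347 were protein-coding. Transcript GC content and length, from GENCODE transcripts, were available for 12174 of the 12333 genes (98.71%).

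The alternatives were DESeq2 size factors, upper-quartile factors, no filter on low counts, at least 1 CPM in 3 samples, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom with sample weights, each background fitted alone, a block of replicate number, a fold change of at least 1.2, and each library left out in turn. Dixon's ratio was applied to CPM in groups of 4 with a mean of at least 1 CPM; a first version on log values had picked genes at 0 counts and was replaced. The edgeR tests within backgrounds, of differences between backgrounds and of controls were tested on simulated counts with 200 changed genes per changed group. DESeq2 and limma-voom within backgrounds, and camera at the preset correlation, were tested there too. The remaining steps were not simulated. Changed genes averaged at least 1 CPM, and no deviation of a single library was simulated. Within backgrounds, edgeR recovered 5.97 to 20.9% of genes changed 1.5-fold, 44.8 to 59.7% of genes changed 2-fold and 86.4 to 92.4% of genes changed 4-fold. For differences between backgrounds it recovered 1.49 to 10.4%, 16.4 to 31.3% and 77.3 to 84.8%, and for controls 7.46 to 11.9%, 52.2 to 67.2% and 89.4 to 97.0%. Within backgrounds the data held a far larger share of called genes (20.3 to 28.5%) than was simulated, so these rates may not hold for the data. In simulated BL6J data over 12333 genes, camera gave an unadjusted p under 0.05 for 2 of 100 random lists. Genes were drawn independently there, so this could not test the effect of correlation between genes on camera.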

Results

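RNA was sequenced from the heart ventricles of male mice in which Taz was knocked out and of littermates that carried the intact gene. Taz encodes tafazzin, the mitochondrial acyltransferase that remodels cardiolipin, the characteristic phospholipid of the inner mitochondrial membrane, and its human counterpart is mutated in Barth syndrome, a disease of heart and skeletal muscle. The gene lies on chromosome X, so that males have a single copy. All mice were 2 months old, and the knockout (KO/Y, here KO) and littermate control (WT/Y, here WT) animals came from 3 genetic backgrounds, named BL6J, AJ-F1 and CAST-F1 in the labels. The 21 libraries fell into 6 groups. BL6J had 4 WT and 4 KO libraries, AJ-F1 had 4 WT and 3 KO libraries, and CAST-F1 had 3 WT and 3 KO libraries. Total counts per library lay between 3848172 and 10738130. The range was 4322220 to 6777826 in BL6J WT and 4408874 to 5545328 in BL6J KO. It was 6579997 to 10738130 in AJ-F1 WT and 5188327 to 7285226 in AJ-F1 KO. It was 5644877 to 6762988 in CAST-F1 WT and 3848172 to 4568610 in CAST-F1 KO. The first principal component of log2 CPM held 39.6% of the variance and separated every KO library from every WT library. Levels are given in CPM, counts divided by the effective library size, as mean ± SD over the libraries of a group, and log2 fold changes of KO over WT as estimate ± standard error (SE), with p-values of the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment.

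Taz itself (chromosome X, 74281900 to 74295319, GRCm38, a protein-coding gene whose annotated span overlaps that of Dnase1l1) was low in every KO library and high in every WT library. The WT libraries held 185 to 609 Taz reads each. Taz stood at 43.8 ± 2.52 CPM in BL6J WT (n = 4), 54.8 ± 5.11 CPM in AJ-F1 WT (n = 4) and 45.3 ± 10.03 CPM in CAST-F1 WT (n = 3). The KO level was 5.84 ± 0.24 CPM in BL6J (n = 4; 28 to 34 reads per library), 2.49 ± 1.17 CPM in AJ-F1 (n = 3; 11 to 20 reads) and 1.98 ± 0.81 CPM in CAST-F1 (n = 3; 5 to 12 reads). These levels were 13.3%, 4.54% and 4.37% of the WT mean of the same background. The log2 fold change of Taz was -2.90 ± 0.20 in BL6J (adjusted p = 5.5e-10), -4.49 ± 0.25 in AJ-F1 (adjusted p = 1.8e-11) and -4.51 ± 0.28 in CAST-F1 (adjusted p = 1.2e-10). The change in AJ-F1 differed from that in BL6J by -1.59 (adjusted p = 0.085), and the change in CAST-F1 differed from that in BL6J by -1.61 (adjusted p = 0.135); neither difference passed the threshold. No library went against its genotype label.

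**Figure D1:**
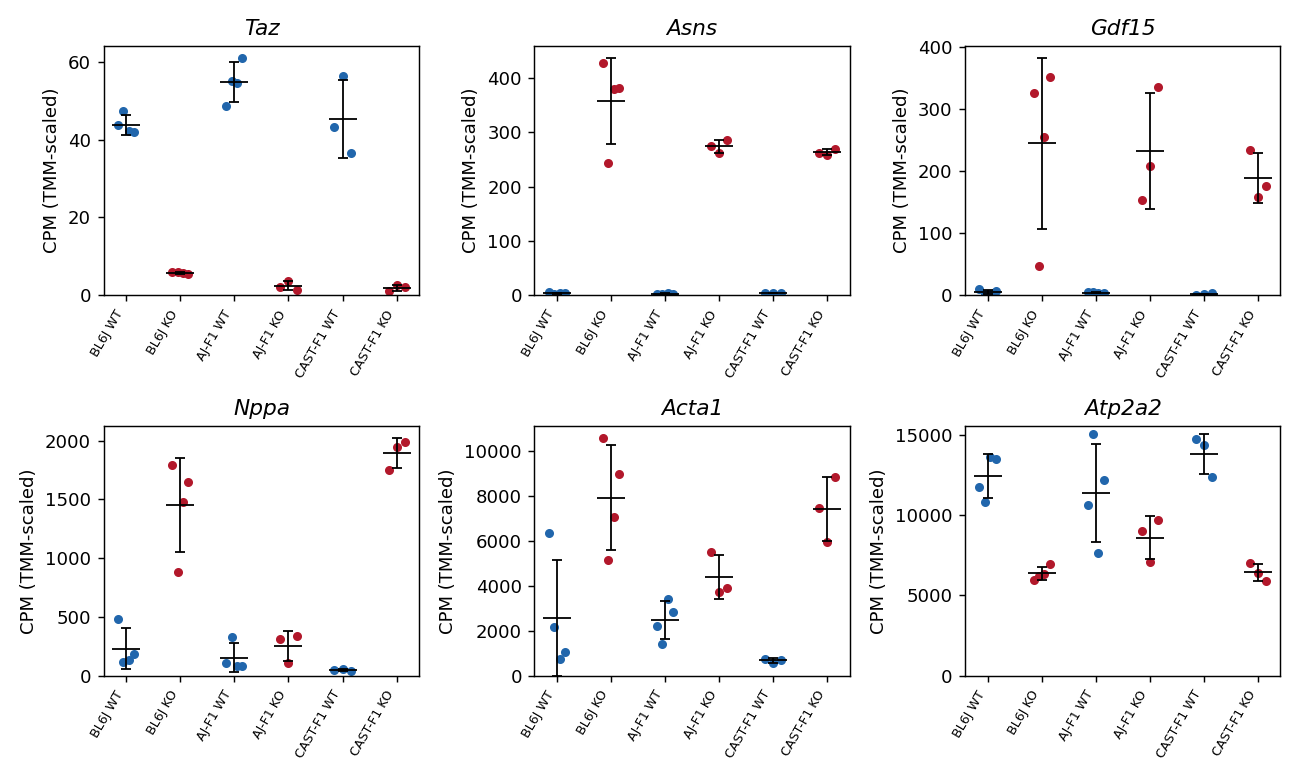
CPM of Taz, Asns, Gdf15, Nppa, Acta1 and Atp2a2 (vertical axes, scaled with TMM factors) in the 6 groups (horizontal axes), where each point is a library, blue for WT and red for KO, and bars give mean ± SD. Taz lies below 7 CPM in every KO library, Asns is high in every KO group, and Nppa averages 1449 CPM in BL6J KO, 253 CPM in AJ-F1 KO and 1897 CPM in CAST-F1 KO.

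The first comparison asked what the loss of Taz changed in the BL6J background. Asns, which encodes asparagine synthetase (chromosome 6, 7675165 to 7693209), rose from 4.18 ± 1.10 CPM in BL6J WT to 358 ± 79.2 CPM in BL6J KO (n = 4 each; log2 fold change 6.40 ± 0.24, adjusted p = 5.4e-14). Mthfd2, a mitochondrial folate enzyme (chromosome 6, 83305704 to 83326011), rose from 2.52 ± 1.60 to 255 ± 36.9 CPM, and Phgdh, which catalyses the first step of serine synthesis, rose from 0.948 ± 0.613 to 155 ± 17.9 CPM (n = 4 each). Atp2a2, the gene of the sarcoplasmic calcium pump (chromosome 5, 122453513 to 122502225), fell from 12428 ± 1370 to 6376 ± 419 CPM (log2 fold change -0.96 ± 0.15, adjusted p = 8.5e-05).

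Among the lists of genes fixed in advance, 19 of the 25 integrated stress response genes rose in BL6J KO and 1 fell, and the counts adjusted over the list alone were 21 and 1. The list covers genes that ATF4 and related factors switch on when translation initiation is restrained. Atf4 itself rose by 2.34 ± 0.17 on the log2 scale, and Atf5, which encodes a related factor that acts in mitochondrial stress, by 3.96 ± 0.23. Trib3, a pseudokinase gene of the same response, rose by 5.68 ± 0.30, and Slc7a5, a subunit gene of a large neutral amino acid transporter, by 4.65 ± 0.22. The single member that fell was Vldlr, a lipoprotein receptor gene named only after its value was seen (-1.11). Of 15 genes of serine, glycine, one-carbon and proline synthesis, 12 rose and 0 fell (14 and 0 adjusted over the list alone), with Pycr1, a proline synthesis gene, at 5.66 ± 0.26 and Psat1, a serine synthesis gene, at 5.38 ± 0.26. Of 20 cytosolic tRNA synthetase genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone), among them Gars at 2.80 ± 0.14 and Sars at 2.56 ± 0.17. These lists kept their calls with an estimated correlation between genes, with adjusted p = 0.0058, 0.0033 and 0.04 with an estimated correlation for stress response, serine and one-carbon and tRNA synthetase genes. Gdf15 (chromosome 8, 70629393 to 70632470) and Fgf21 (chromosome 7, 45613890 to 45615490) encode secreted signals released by stressed tissue. Gdf15 rose from 5.43 ± 3.86 to 246 ± 138 CPM (adjusted p = 3.6e-07). Fgf21 had 2 reads in the WT libraries together and 1090 in the KO libraries, a ratio of 537 with a 95% counting interval of 148 to 4443. Such intervals, and floors for genes without reads, cover counting error only.

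Of 20 fatty acid oxidation genes, 13 fell and 0 rose in BL6J KO (15 and 0 adjusted over the list alone; camera adjusted p = 1.6e-08, and adjusted p = 0.13 with an estimated correlation). Acaa2, a thiolase gene, fell by 0.89 on the log2 scale and Acsl1, which activates long-chain fatty acids, fell by 0.90. Of 60 nuclear genes of oxidative phosphorylation, 22 fell and 0 rose (23 and 0 adjusted over the list alone; adjusted p = 4.0e-07, and adjusted p = 0.63 with an estimated correlation). Cox7a1, a heart and muscle subunit gene of cytochrome oxidase, had a log2 fold change of -1.31 ± 0.17 and Uqcrfs1, the Rieske protein gene of complex III, of -0.68 ± 0.11. Of 17 tricarboxylic acid cycle genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.00074, and adjusted p = 0.43 with an estimated correlation), led by Idh2 at -0.70 ± 0.11. Of 18 genes of mitochondrial protein quality control, 6 rose and 0 fell (7 and 2 adjusted over the list alone; adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation). Lonp1, the matrix protease gene, rose by 1.88 ± 0.13 on the log2 scale.

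Hypertrophy and fetal genes rose in BL6J KO for 13 of 19 members and fell for 2 (13 and 2 adjusted over the list alone; adjusted p = 8.7e-06, and adjusted p = 0.35 with an estimated correlation). Nppa, the atrial natriuretic peptide gene that ventricles switch on under load (chromosome 4, 148000722 to 148002074), rose from 229 ± 173 to 1449 ± 401 CPM (n = 4 each; adjusted p = 0.00053). Uchl1, a ubiquitin hydrolase gene, rose by 3.84 ± 0.21, Nmrk2, a kinase gene of NAD synthesis in muscle, by 3.97 ± 0.32, and Ankrd1, a titin-associated stress gene, by 1.93 ± 0.32. Acta1, the skeletal actin gene, rose by 1.62 ± 0.46. Leaving out BL6J WT 1, the highest WT library for these genes, gave 2.58 for Acta1, 3.34 in place of 2.66 for Nppa and 4.62 for Nmrk2. The members that fell were Mybpc2, which encodes the fast skeletal form of myosin-binding protein C (-2.16 ± 0.28), and Tnnt1, the slow skeletal troponin T gene, named after its value was seen (-1.31). Of 25 genes of mature cardiomyocyte function, 15 fell and 0 rose (16 and 1 adjusted over the list alone; adjusted p = 8.2e-07, and adjusted p = 0.068 with an estimated correlation), with Hcn4, a pacemaker channel gene, at -2.76 ± 0.35 and Kcnj3, a potassium channel gene, at -2.15 ± 0.34. Of 16 antioxidant response genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 8.7e-06, and adjusted p = 0.12 with an estimated correlation), among them Srxn1, the sulfiredoxin gene, at 2.12 ± 0.19. Of 18 immediate early genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.70 with an estimated correlation), with Jun, a transcription factor gene, at -1.75 ± 0.34.

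Several genes that rose in BL6J KO had almost no reads in WT. Soat2, a cholesterol esterification gene, had 0 reads in WT and 751 in KO, which makes it at least 247-fold higher against a floor of 3 counts over the group. Adm2, a peptide hormone gene, had 2 reads in WT and 1366 in KO, and Ostn, the gene of the muscle peptide osteocrin, had 2 and 1028. The largest falls included Clcn1, the muscle chloride channel gene (-4.61 ± 0.51), Aqp4, a water channel gene (-3.97 ± 0.57), Myot, the gene of the Z-disc protein myotilin (-3.55 ± 0.27), and Scn4a, the skeletal muscle sodium channel gene (-3.25 ± 0.35). Across 12333 genes tested, 1583 rose and 1173 fell in BL6J KO, 2756 in all. The rises of Nppb (1.27 ± 0.44, adjusted p = 0.045) and Myh7 (2.04 ± 0.67, adjusted p = 0.036) were no longer called under 21 and 10 of the other settings and libraries left out, and that of Acta1 was lost when each background was fitted alone (adjusted p = 0.151). Myh7 stood at 3.29 without BL6J WT 1 and at 1.14 without BL6J KO 4 (adjusted p = 0.203), Clcn1 at -5.49 without BL6J KO 2 and Aqp4 at -4.90 without BL6J KO 3. Calls numbered 4247 with limma-voom and sample weights and 1829 against a fold change of at least 1.2.

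**Figure D2:**
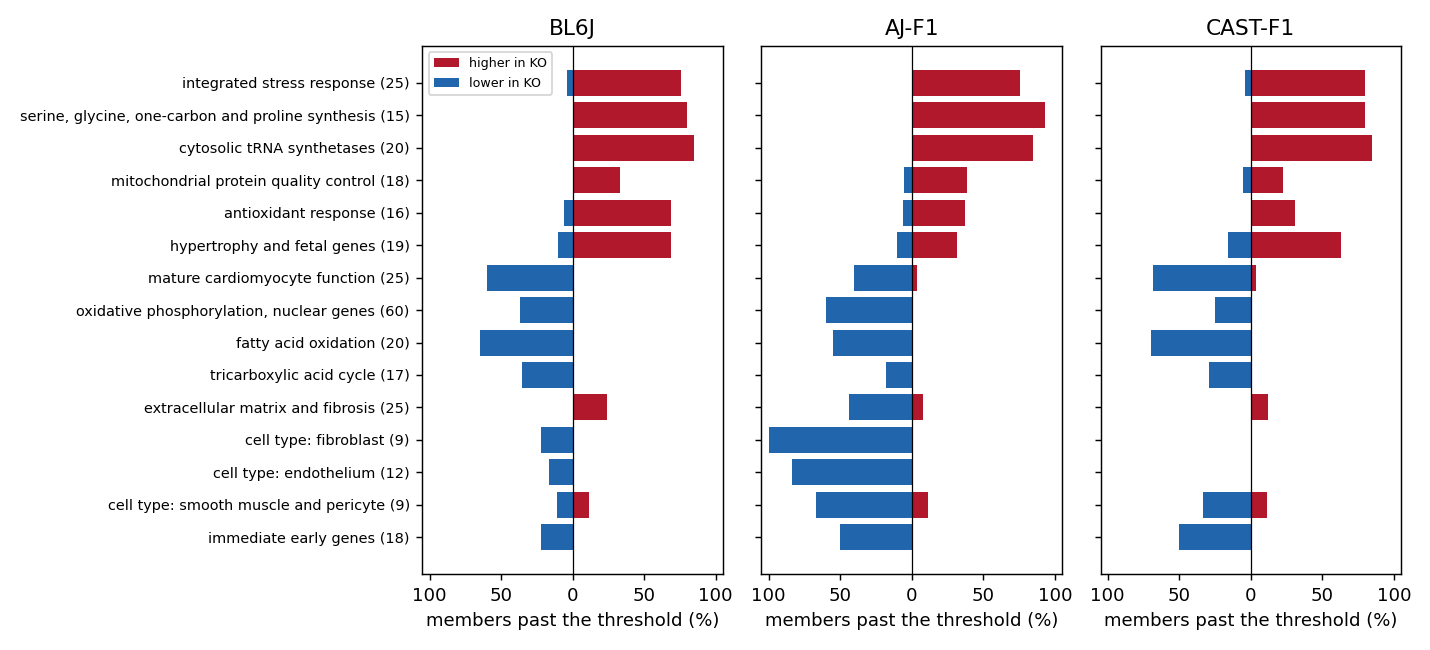
Percent of the tested members of each gene list past the threshold (horizontal axes; the number of tested members in parentheses), drawn to the right in red for members higher in KO and to the left in blue for members lower in KO, for BL6J, AJ-F1 and CAST-F1. The top 3 lists lean to the right in every background, and the fibroblast and endothelium lists lean to the left most in AJ-F1, with 9 of 9 and 10 of 12 members lower.

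The second comparison put the same question to the AJ-F1 background. Stress response and amino acid genes rose there too. Asns rose from 3.20 ± 1.39 CPM in AJ-F1 WT (n = 4) to 274 ± 11.8 CPM in AJ-F1 KO (n = 3; log2 fold change 6.44 ± 0.25, adjusted p = 3.3e-14), Mthfd2 from 0.615 ± 0.145 to 200 ± 11.1 CPM and Gdf15 from 4.65 ± 1.45 to 233 ± 94.0 CPM. Nppa stood at 153 ± 121 CPM in AJ-F1 WT and 253 ± 129 CPM in AJ-F1 KO and did not pass the test (log2 fold change 0.73 ± 0.50, adjusted p = 0.29). Nor did Acta1 (0.83 ± 0.48, adjusted p = 0.21), Nppb (-0.59 ± 0.48, adjusted p = 0.37) or Atp2a2 (-0.40 ± 0.17, adjusted p = 0.075). For Nppa and Atp2a2 this rested on single AJ-F1 WT libraries. Nppa was at 333 CPM in AJ-F1 WT 2 and 83.1 to 110 CPM in the other WT libraries, and without that library it passed the test (1.45, adjusted p = 0.025). Atp2a2 passed without AJ-F1 WT 3 (-0.56, adjusted p = 0.0052) and with limma-voom and sample weights (adjusted p = 0.022). Acta1 passed without BL6J WT 1 (adjusted p = 0.0496), a library outside the AJ-F1 comparison, which left the change at 0.83. Their changes did not differ from those in BL6J past the threshold either, with a difference of -1.93 ± 0.70 for Nppa (adjusted p = 0.362), -0.79 ± 0.67 for Acta1 (adjusted p = 0.663), -1.86 ± 0.66 for Nppb (adjusted p = 0.345) and 0.56 ± 0.23 for Atp2a2 (adjusted p = 0.391).

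In AJ-F1 KO, 19 of 25 integrated stress response genes rose and 0 fell (19 and 0 adjusted over the list alone), 14 of 15 serine, glycine, one-carbon and proline genes rose (15 adjusted over the list alone) and 17 of 20 tRNA synthetase genes rose (17 adjusted over the list alone). Their adjusted p was 0.02, 0.0036 and 0.038 with an estimated correlation. Atf4 rose by 2.13 ± 0.17 and Trib3 by 5.08 ± 0.29, Phgdh by 7.18 ± 0.33, and Eprs, the gene of glutamyl-prolyl-tRNA synthetase, by 2.88 ± 0.23. Of the 60 oxidative phosphorylation genes, 36 fell and 0 rose (43 and 0 adjusted over the list alone; adjusted p = 4.5e-11, and adjusted p = 0.30 with an estimated correlation), with Cox8b, a muscle subunit gene of cytochrome oxidase, at -1.44 ± 0.18 and Cox6c at -0.89 ± 0.15. Of the 20 fatty acid oxidation genes, 11 fell (12 adjusted over the list alone; adjusted p = 3.6e-05, and adjusted p = 0.30 with an estimated correlation), among them Hadh at -0.95 ± 0.13 and Acads, a short-chain acyl-CoA dehydrogenase gene, at -1.14 ± 0.16. Mitochondrial protein quality control genes rose for 7 of 18 members and fell for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.30 with an estimated correlation), with Lonp1 at 2.14 ± 0.13 and Hspa9, the mitochondrial HSP70 gene, at 1.61 ± 0.21. Mature cardiomyocyte genes fell for 10 of 25 members and rose for 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.30 with an estimated correlation). Hcn4 had a log2 fold change of -2.99 ± 0.37, and the member that rose was Slc8a1, the sodium-calcium exchanger gene (1.42 ± 0.25). The hypertrophy and fetal list was not called (6 members rose, 2 fell, 6 and 2 adjusted over the list alone; adjusted p = 0.16), although Uchl1 (2.93 ± 0.22), Nmrk2 (3.87 ± 0.33) and Ankrd1 (1.69 ± 0.33) rose.

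All 9 fibroblast markers tested fell in AJ-F1 KO (9 adjusted over the list alone; adjusted p = 8.7e-05, and adjusted p = 0.30 with an estimated correlation). Gsn, the gelsolin gene, fell from 885 ± 363 to 332 ± 10.5 CPM and Dcn, the decorin gene, from 343 ± 65.7 to 190 ± 17.1 CPM. Of 12 endothelium markers, 10 fell (12 adjusted over the list alone; adjusted p = 4.3e-05, and adjusted p = 0.30 with an estimated correlation). Pecam1, which encodes an endothelial adhesion molecule, fell from 216 ± 61.2 to 104.99 ± 20.7 CPM, and Cav1, the caveolin gene, from 368 ± 59.0 to 163 ± 49.6 CPM. Smooth muscle and pericyte markers fell for 6 of 9 members and rose for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.30 with an estimated correlation). Myh11, the smooth muscle myosin gene, had a log2 fold change of -1.94 ± 0.29, whereas Acta2, the smooth muscle actin gene that fetal and stressed heart muscle also expresses, rose by 1.54 ± 0.24. Nerve and glia markers fell for 4 of 5 members (4 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.078 with an estimated correlation). Dbh, which encodes the enzyme that makes noradrenaline, had 404 reads in WT and 3 in KO, 80.5 times lower with a counting interval of 27.4 to 392. Dbh was also called lower in BL6J KO (5.80 ± 1.61 to 0.534 ± 0.526 CPM) and in CAST-F1 KO (102 reads in WT and 3 in KO). Extracellular matrix genes fell for 11 of 25 members and rose for 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0074, and adjusted p = 0.47 with an estimated correlation), with Sparc, a matrix glycoprotein gene, at -1.17 ± 0.24 and Tgfb2, a growth factor gene, rising by 1.98 ± 0.35. Circadian clock genes fell for 8 of 15 members (8 fell and 2 rose adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.30 with an estimated correlation), with Hlf at -2.36 ± 0.29 and Dbp at -3.78 ± 0.77. The WT libraries stood apart in Dbp, with 38.5, 84.1, 525 and 337 CPM in AJ-F1 WT 1 to 4, and its change was -3.10 without AJ-F1 WT 3. Immediate early genes fell for 9 of 18 members (10 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.52 with an estimated correlation), and fry did not call the list (0.0516). Mesothelium markers rose for 5 of 8 members (6 adjusted over the list alone; adjusted p = 0.0077, and adjusted p = 0.30 with an estimated correlation), with Lrrn4 at 1.81 ± 0.41.

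The AJ-F1 WT libraries were spread out, and AJ-F1 WT 3 lay furthest apart. On the third principal component, AJ-F1 WT 3 and 4 stood at -61.2 and -20.6, and AJ-F1 WT 1 and 2 at 7.33 and 20.2. AJ-F1 WT 2 and 4 correlated with r of 0.958, against 0.980 for AJ-F1 WT 1 and 2. Leaving out AJ-F1 WT 3 alone therefore does not remove all of this spread. AJ-F1 WT 3 deviated from the other AJ-F1 WT libraries by a root mean square of 0.855 on the log2 scale, against 0.349 to 0.634 in the other 20 libraries, and its deviation followed the GC content of transcripts (Spearman's rho across genes 0.732; genes are not independent replicates). Without it every one of the AJ-F1 lists called above was still called, with 8 of 9 fibroblast, 6 of 12 endothelium and 7 of 9 smooth muscle and pericyte markers lower, 7 of 25 extracellular matrix genes lower and 27 of 60 oxidative phosphorylation genes lower. Immediate early genes were then lower for 5 of 18 members. With camera, the antioxidant response list was called in AJ-F1 only without AJ-F1 WT 3 (adjusted p = 0.0474). The fry test called that list with all libraries. Across all genes, 1588 rose and 1933 fell in AJ-F1 KO, 3521 in all. Without AJ-F1 WT 3 the count was 3349, of which 2849 were also among the 3521, and without AJ-F1 KO 3 it was 2135. Fitted alone, AJ-F1 gave 1323 genes. The collagen genes Col1a1 (-0.99 ± 0.34, adjusted p = 0.033) and Col3a1 (-0.72 ± 0.25, adjusted p = 0.033) were not called without AJ-F1 WT 3.

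**Figure D3:**
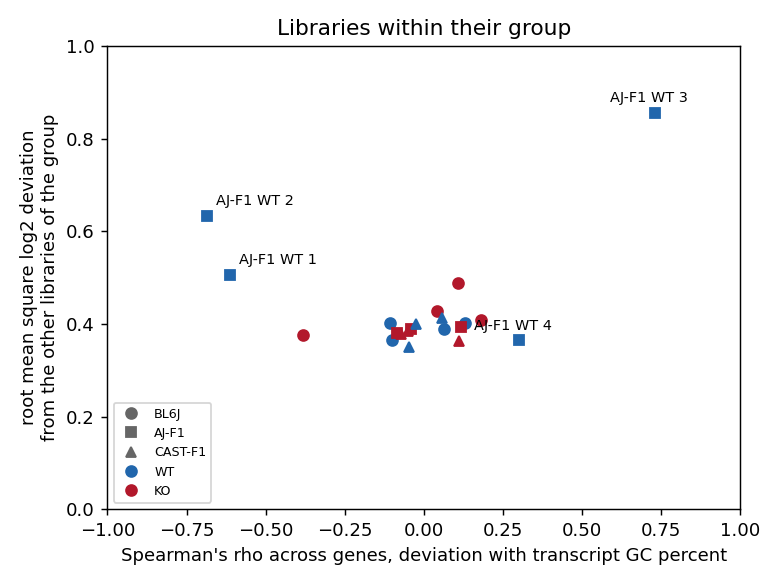
Each point is a library, with Spearman's rho across genes between its deviation from the other libraries of its group and transcript GC percent on the horizontal axis and the root mean square of that deviation (log2 scale) on the vertical axis; blue is WT, red is KO, and shapes mark the backgrounds. AJ-F1 WT 3 lies apart with a rho of 0.732 and a deviation of 0.855, and AJ-F1 WT 2 follows with -0.686 and 0.634.

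Genes that rose in AJ-F1 KO from almost no reads in WT included Ostn (0 reads in WT and 962 in KO, at least 536-fold higher) and Adm2 (0 and 947 reads, at least 528-fold higher). Fgf21 had 1 and 728 reads, and Vgll2, a transcription cofactor gene of skeletal muscle, had 1 and 708. The largest falls, beside Dbh, included Lypd2 (-4.31 ± 0.62), Acsm5, a medium-chain acyl-CoA synthetase gene (-3.91 ± 0.45), Clcn1 (-3.87 ± 0.50) and Scn4a (-3.63 ± 0.41).

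The third comparison concerned the CAST-F1 background. Asns rose from 3.88 ± 0.09 CPM in CAST-F1 WT to 263 ± 5.55 CPM in CAST-F1 KO (n = 3 each; log2 fold change 6.08 ± 0.28, adjusted p = 1.3e-12), Mthfd2 from 0.679 ± 0.120 to 217 ± 8.78 CPM and Gdf15 from 1.75 ± 1.28 to 190 ± 40.0 CPM (log2 fold change 6.73, and 7.40 without CAST-F1 WT 3). Nppa rose from 45.9 ± 9.71 to 1897 ± 126 CPM (log2 fold change 5.37 ± 0.65, adjusted p = 5.9e-06) and Acta1 from 676 ± 96.2 to 7425 ± 1445 CPM (adjusted p = 0.0002). Atp2a2 fell from 13829 ± 1257 to 6432 ± 548 CPM (log2 fold change -1.10 ± 0.18, adjusted p = 0.00012), and Kcnj3 from 72.6 ± 8.31 to 7.22 ± 1.69 CPM.

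Of the 25 integrated stress response genes, 20 rose and 1, again Vldlr, fell in CAST-F1 KO (21 and 1 adjusted over the list alone). Of the serine, glycine, one-carbon and proline genes, 12 of 15 rose (13 adjusted over the list alone), and of the tRNA synthetase genes 17 of 20 (18 adjusted over the list alone). Their adjusted p was 0.0078, 0.0064 and 0.045 with an estimated correlation. Atf4 rose by 2.13 ± 0.19, Ddit3, which encodes the stress factor CHOP, by 2.32 ± 0.27 and Trib3 by 6.19 ± 0.35. Fatty acid oxidation genes fell for 14 of 20 members (15 adjusted over the list alone; adjusted p = 4.6e-07, and adjusted p = 0.24 with an estimated correlation), with Cpt2, which encodes the inner membrane carnitine transferase, at -0.99 ± 0.15. Oxidative phosphorylation genes fell for 15 of 60 members (15 adjusted over the list alone; adjusted p = 2.5e-05, and adjusted p = 0.64 with an estimated correlation), with Cox8b at -1.27 ± 0.18. Tricarboxylic acid cycle genes fell for 5 of 17 members (6 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.64 with an estimated correlation), with Idh2 at -1.10 ± 0.13. Hypertrophy and fetal genes rose for 12 of 19 members and fell for 3 (12 and 3 adjusted over the list alone; adjusted p = 9.9e-06, and adjusted p = 0.40 with an estimated correlation). Among them were Nppb, the brain natriuretic peptide gene (2.01 ± 0.52), Uchl1 (3.38 ± 0.26) and Ctgf, a matricellular protein gene (2.62 ± 0.46). Mature cardiomyocyte genes fell for 17 of 25 members and rose for 1 (17 and 2 adjusted over the list alone; adjusted p = 3.2e-06, and adjusted p = 0.088 with an estimated correlation). Hcn4 stood at -4.20 ± 0.53 (-5.07 without CAST-F1 KO 3) and Myh6, the adult cardiac myosin gene, at -0.82 ± 0.18. Immediate early genes fell for 9 of 18 members (13 adjusted over the list alone; adjusted p = 1.8e-05, and adjusted p = 0.45 with an estimated correlation), with Fos at -3.57 ± 0.71. Mitochondrial protein quality control genes rose for 4 of 18 members and fell for 1 (4 and 1 adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.64 with an estimated correlation). Endoplasmic reticulum chaperone genes fell for 5 of 17 members and rose for 1 (8 and 2 adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.59 with an estimated correlation). Mesothelium markers rose for 4 of 8 members (6 adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation). None of the 9 fibroblast and 12 endothelium markers passed the test in CAST-F1.

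Genes that rose in CAST-F1 KO from almost no reads in WT included Adm2 (0 and 716 reads, at least 316-fold higher), Ostn (0 and 681 reads, at least 300.2-fold higher) and Fgf21 (1 and 506 reads). Gucy2e, a guanylate cyclase gene, had 155 reads in WT and 1 in KO, Scn4a had a log2 fold change of -5.79 ± 0.63, and Scn4b, a sodium channel subunit gene, of -4.95 ± 0.58. In all, 1315 genes rose and 1183 fell in CAST-F1 KO, a total of 2498. Counts were 4939 with limma-voom and sample weights and 4100 when CAST-F1 was fitted alone, and the call of Nppb was lost without CAST-F1 WT 1 (adjusted p = 0.0504). The change of Scn4a was -5.19 without CAST-F1 KO 1 and -6.55 without CAST-F1 KO 3.

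Set side by side, the backgrounds shared a large part of the response. In all 3 backgrounds 739 genes rose and 588 fell, 1327 of the 4971 genes called in any background, where independent lists of these sizes would share 21.7 and 17.6. The genes shared with the largest minimum fitted change were B4galnt2, Adm2, Vmn2r3, Fgf21, Ostn, Fam227b, Cyb5r2, Soat2, Slc7a3 and Akr1b7, all of which rose. B4galnt2, a glycosyltransferase gene (chromosome 11, 95863559 to 95914960), had 0 reads in the 11 WT libraries and stood at 18.5 ± 6.06 CPM in BL6J KO (n = 4), 17.0 ± 6.75 CPM in AJ-F1 KO (n = 3) and 36.4 ± 5.76 CPM in CAST-F1 KO (n = 3). Adm2 (chromosome 15, 89322720 to 89324731) reached 63.3 ± 22.0, 51.2 ± 7.64 and 53.8 ± 6.55 CPM, and Ostn (chromosome 16, 27307641 to 27351209) 47.6 ± 18.3, 52.5 ± 5.03 and 51.0 ± 9.15 CPM in the same groups. Log2 fold changes correlated across the 12333 genes with Pearson's r of 0.778 between BL6J and AJ-F1, 0.826 between BL6J and CAST-F1 and 0.772 between AJ-F1 and CAST-F1 (Spearman's rho 0.670, 0.751 and 0.681), as a description across genes that are not independent replicates. Of the genes called in either background of a pair, 92.2%, 97.0% and 92.6% had the same sign. The backgrounds shared no control library. On average over the 3 backgrounds, 2925 genes rose and 2987 fell.

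**Figure D4:**
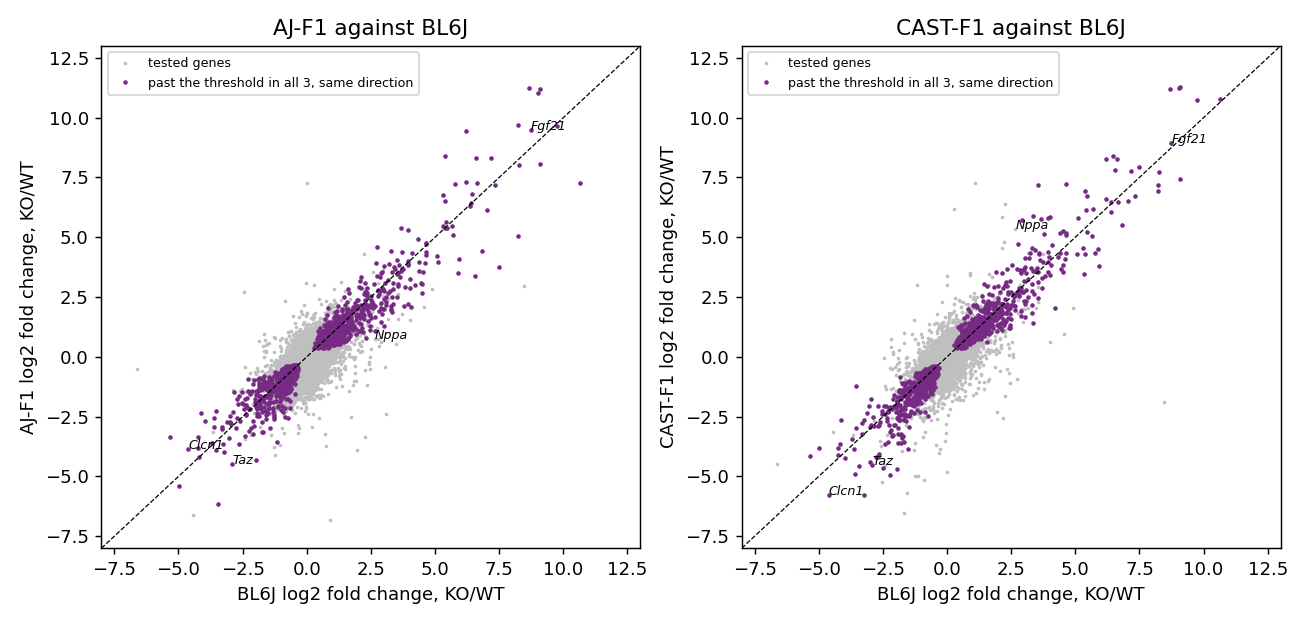
Log2 fold changes of KO over WT in AJ-F1 (left) and CAST-F1 (right) on the vertical axes against those in BL6J on the horizontal axes, where each point is a tested gene, purple for the 1327 genes called in the same direction in all 3 backgrounds, and the dashed line marks equal change. Points follow the line, with r of 0.778 on the left and 0.826 on the right, and Nppa lies under it in AJ-F1 (0.73) and above it in CAST-F1 (5.37).

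The next question was which genes responded differently between backgrounds, tested as the difference of the changes themselves. Few single genes passed. The change of Nppa was higher in CAST-F1 than in AJ-F1 by 4.64 ± 0.79 on the log2 scale (adjusted p = 0.036), and that of Acta2 by 2.01 ± 0.37. Kif5a, a neuronal kinesin gene (chromosome 10, 127225695 to 127266348), rose from 0.961 ± 0.293 to 52.6 ± 5.40 CPM in CAST-F1 and from 1.44 ± 0.51 to 11.2 ± 1.85 CPM in BL6J, a difference of 2.80 ± 0.42 (adjusted p = 0.013). It differed from AJ-F1 by 2.18 ± 0.41 (adjusted p = 0.04). Hyal1, a hyaluronidase gene (chromosome 9, 107576950 to 107581699), went from 5.75 ± 1.37 to 21.6 ± 6.45 CPM in BL6J and from 9.75 ± 2.91 to 7.30 ± 1.72 CPM in AJ-F1, a difference of -2.29 ± 0.37 (adjusted p = 0.038).

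Between AJ-F1 and BL6J, 0 genes had a higher and 1 a lower change (Hyal1). The edgeR test gave 1371 genes at an unadjusted p under 0.05, DESeq2 called 72 genes and limma-voom 14. Between CAST-F1 and BL6J, 3 genes had a higher change (Kif5a, 1810010H24Rik and Bckdhb, a gene of branched-chain amino acid breakdown) and 1 a lower change (Fmn1, a formin gene). The genes 1810010H24Rik and Lpin1 were named after their values were seen. Here 597 genes had an unadjusted p under 0.05, and DESeq2 called 27 and limma-voom 72. Without any true difference, about 5% of the 12333 genes tested would have such a p, and the 597 genes do not exceed that share. Between CAST-F1 and AJ-F1, 9 genes had a higher change and 2 a lower one (Best3, a chloride channel gene, and Lpin1, a phosphatidate phosphatase gene), with 1219 at an unadjusted p under 0.05 and 86 by DESeq2 and 133 by limma-voom. Psca, a cell surface gene, was at 15.97 ± 2.05 CPM in CAST-F1 KO and at 0 reads in AJ-F1 KO. Slc1a4, a neutral amino acid transporter gene, differed by 2.99 ± 0.56 and Kcne1, a potassium channel subunit gene, by 2.28 ± 0.40. The difference of Nppa was not called without AJ-F1 WT 3 (4.88 ± 0.89, adjusted p = 0.0566) or in 14 other settings and libraries left out, and was 3.91 without AJ-F1 WT 2 (adjusted p = 0.0453). That of Hyal1 was lost in 15. Other differences of CAST-F1 from AJ-F1 were lost in 20 for Myl9, 19 for Cyp51, 18 for Kif5a, 18 for Best3, 14 for Slc1a4, 12 for Psca, 11 for Acta2 and 10 for Kcne1. Differences of CAST-F1 from BL6J were lost in 23 for Fmn1, 17 for Bckdhb and 5 for Kif5a.

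At the level of lists, extracellular matrix genes had lower changes in AJ-F1 than in BL6J (median difference -0.94; adjusted p = 7.8e-10, and adjusted p = 0.22 with an estimated correlation). Fibroblast markers (-0.72; adjusted p = 0.00014, and adjusted p = 0.29 with an estimated correlation) and smooth muscle and pericyte markers (-1.10; adjusted p = 0.00079, and adjusted p = 0.29 with an estimated correlation) also had lower changes in AJ-F1 than in BL6J. Adjusted over the list alone, 15 of 25 extracellular matrix genes differed between AJ-F1 and BL6J, against 0 over all genes. Hypertrophy and fetal genes had lower changes in AJ-F1 than in BL6J (median difference -0.79; adjusted p = 1.9e-05, and adjusted p = 0.32 with an estimated correlation). They had higher changes in CAST-F1 than in AJ-F1 (0.56; adjusted p = 2.7e-06, and adjusted p = 0.30 with an estimated correlation). Endoplasmic reticulum chaperones had lower changes in CAST-F1 than in AJ-F1 (-0.56; adjusted p = 2.2e-06, and adjusted p = 0.25 with an estimated correlation). Of the 30 lists tested, camera called 11 between AJ-F1 and BL6J, 4 between CAST-F1 and BL6J and 12 between CAST-F1 and AJ-F1; with an estimated correlation it called 0 in each, and the rotation test fry called 2, 0 and 1.

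The WT libraries were compared to see how the hearts of the backgrounds differed with Taz intact. The test called 246 genes higher and 156 lower in AJ-F1 WT than in BL6J WT, and 415 higher and 292 lower in CAST-F1 WT than in BL6J WT. Rab6b, a GTPase gene of vesicle traffic (chromosome 9, 103111667 to 103185276), was at 18.4 ± 2.06 CPM in BL6J WT, 1.58 ± 0.75 CPM in AJ-F1 WT and 2.00 ± 0.09 CPM in CAST-F1 WT. Ddc, which encodes aromatic amino acid decarboxylase, was at 5.63 ± 0.60 CPM in BL6J WT and 0.340 ± 0.154 CPM in CAST-F1 WT. Of 17 interferon response genes, 8 were lower and 1 higher in CAST-F1 WT than in BL6J WT (9 and 1 adjusted over the list alone; adjusted p = 7.6e-09, and adjusted p = 0.18 with an estimated correlation). In AJ-F1 WT, 2 of them were lower (6 adjusted over the list alone; adjusted p = 0.00094, and adjusted p = 0.46 with an estimated correlation). Of 60 oxidative phosphorylation genes, 9 were higher in CAST-F1 WT (21 adjusted over the list alone; adjusted p = 7.6e-09, and adjusted p = 0.85 with an estimated correlation).

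The largest differences between the controls lay in genes with near-identical copies. Eno1b, a retrocopy of the enolase gene Eno1, stood at 0.057 ± 0.114 CPM in BL6J WT, 37.7 ± 9.73 CPM in AJ-F1 WT and 74.5 ± 7.40 CPM in CAST-F1 WT. Gapdh-ps15, annotated as a pseudogene, stood at 1.91 ± 1.25 CPM in BL6J WT and 2819 ± 123 CPM in CAST-F1 WT, and Rpl34-ps1 at 0.098 ± 0.113 and 44.1 ± 4.44 CPM. Reads of such copies and of their parent genes can be assigned to either, so these values are uncertain as measures of the copy itself. The beta-globin gene Hbb-b1, which has close paralogs and belongs to a haplotype that only some inbred strains carry, had 0 reads in BL6J WT and stood at 94.2 ± 103 CPM in AJ-F1 WT, with 240 CPM in AJ-F1 WT 3 and 4.62, 41.6 and 90.3 CPM in the others. Its difference was not called with limma-voom and sample weights (adjusted p = 0.218). Of the 402 genes that differed between AJ-F1 and BL6J controls, 61.2% were higher in AJ-F1, a share of 48.7% with the GC trend of each library removed. The count was 257 without AJ-F1 WT 3 and 2065 without AJ-F1 WT 2.

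With camera, the remaining lists gave no call in the within-background comparisons, apart from endothelium markers in BL6J, given below. The fry test also called nerve and glia markers in BL6J and CAST-F1 (adjusted p = 0.0067 and 0.0046), antioxidant response genes in AJ-F1 and CAST-F1 (0.009 and 0.033), muscle protein degradation genes in AJ-F1 (0.016) and cardiolipin genes in CAST-F1 (0.012). The cardiolipin list holds Taz itself, whose fall was set by the knockout. The list was not tested with fry without Taz, so this call says nothing certain about its other members. Cardiolipin synthesis and remodelling genes rose for 1, 2 and 2 and fell for 2, 1 and 3 of 15 members in BL6J, AJ-F1 and CAST-F1 (the same counts adjusted over the list alone), Taz among those that fell. Glycolysis and glucose uptake genes rose for 5, 6 and 6 and fell for 5, 6 and 6 of 20 members, with Pfkp, a phosphofructokinase gene, at 1.39 ± 0.15, 1.66 ± 0.16 and 1.34 ± 0.18 and Eno3, the muscle enolase gene, at -1.22 ± 0.18, -1.45 ± 0.20 and -1.63 ± 0.21. Adjusted over the list alone, these counts were 7, 6 and 7 up and 6, 6 and 7 down. PPAR target genes rose for 2, 2 and 1 and fell for 5, 5 and 4 of 15 members (2, 2 and 4 up and 5, 5 and 5 down adjusted over the list alone), with Acot2, a mitochondrial thioesterase gene, rising by 2.17 ± 0.22 in AJ-F1 and 2.07 ± 0.25 in CAST-F1. Cristae, fusion and fission genes rose for 2, 2 and 2 and fell for 3, 2 and 1 of 15 members (2, 3 and 2 up and 4, 3 and 1 down adjusted over the list alone), with Ghitm, an inner membrane protein gene, rising from 378 ± 6.73 to 1147 ± 111 CPM in BL6J. Muscle protein degradation genes rose for 3, 4 and 4 and fell for 2, 2 and 3 of 14 members, and cholesterol synthesis genes rose for 2, 1 and 3 and fell for 1, 3 and 2 of 16 members. Adjusted over the list alone, the counts were the same apart from cholesterol synthesis in CAST-F1, with 5 up and 3 down.

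Antioxidant response genes rose for 6 of 16 members in AJ-F1 and for 5 in CAST-F1 and fell for 1 in AJ-F1 (6 and 5 rose and 1 and 1 fell adjusted over the list alone; adjusted p = 0.096 and 0.11). Tricarboxylic acid cycle genes fell for 3 of 17 members in AJ-F1 (3 adjusted over the list alone; adjusted p = 0.58). Extracellular matrix genes rose for 6 and 3 of 25 members in BL6J and CAST-F1 (6 and 3 adjusted over the list alone; adjusted p = 0.062 and 0.19). In the order BL6J, AJ-F1 and CAST-F1, members past the threshold in either direction numbered 2, 3 and 2 of 7 cell cycle genes, 0, 5 and 1 of 17 interferon response genes and 0, 1 and 0 of 12 macrophage markers. They numbered 2, 1 and 2 of 10 atrium markers and 0, 0 and 0 of 5 erythroid markers. Without AJ-F1 WT 3, 1 of 16 interferon response genes tested passed in AJ-F1. Endothelium markers were called in BL6J with 2 of 12 members lower (2 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.70 with an estimated correlation). Median, mean and test direction differed in sign, with no call by camera, for glycolysis in BL6J and CAST-F1, for cristae, cell cycle and protein degradation genes in BL6J and CAST-F1, for macrophage markers in AJ-F1 and for cardiolipin genes and atrium markers in CAST-F1. The atrium markers in CAST-F1 had a median of 1.00, or 0.62 with a member of few reads at its bound. Atf5, Ddit3, Myh6, Clcn1, Mybpc2, Cyb5r2, Fam227b, Slc7a3, Hyal1, Kif5a, Dbp, Lrrn4, Pfkp and Eno3 overlap other annotated genes, and their values are uncertain to that extent because the use of strand in counting was not given in the sources used here. Lymphocyte, neutrophil, adipocyte and mixed tissue markers had fewer than 3 tested members each, and genes of the mitochondrial genome were not analysed here.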

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

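The tests of GC content, female RNA, atrial tissue, the AJ-F1 WT 3 library, a smaller response, Dnase1l1 reads, mixed RNA and scaling were chosen after the results they address were seen. The count of AJ-F1 calls with the GC trend removed was added after the data were seen, with its criterion written before that count was made, and the splits of the samples were fixed before they were fitted.

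Several genes changed by different amounts between backgrounds in a test of the difference itself. On the log2 scale, the change of Hyal1 was lower in AJ-F1 than in BL6J (-2.29). The changes of Kif5a (2.80), Bckdhb (1.04) and 1810010H24Rik (2.62) were higher in CAST-F1 than in BL6J, and that of Fmn1 was lower (-2.67). Against AJ-F1, CAST-F1 had higher changes of Nppa (4.64), Psca (9.73), Slc1a4 (2.99), Kcne1 (2.28), Kif5a (2.18), Acta2 (2.01), Myl9, a myosin light chain gene (2.01), Slc38a4, an amino acid transporter gene (1.72), and Cyp51, a cholesterol synthesis gene (1.36), and lower changes of Best3 (-2.04) and Lpin1 (-1.27). Most of these calls were lost in other settings or with a library left out, among them Myl9 in 20 (adjusted p up to 0.191) and Cyp51 in 19 (up to 0.361). The value of Psca is a fitted one, since AJ-F1 KO had no reads, and is no bound. Of the lists, fry called the extracellular matrix (median difference -0.94) and nerve and glia (-1.67) lists between AJ-F1 and BL6J and the endoplasmic reticulum chaperones (-0.56) between CAST-F1 and AJ-F1.

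Single libraries stood far from the others of their group in 13 of 194 sets of 4 values, tested by the gap of the extreme library relative to the range. Each set was a named gene, the Taz level or the total count in BL6J WT, BL6J KO or AJ-F1 WT. Chance gives about 1 in 20, and the flags were near that share, so any of them may be chance. That share is approximate, since the sets are not independent and many genes were chosen from the same data. Ankrd1 was at 2040 CPM in BL6J WT 1 and 720 to 923 CPM in the others (ratio 0.846). Atf5 was at 28.7 CPM in BL6J WT 3 against 46.2 to 48.7 CPM (0.875), and Egf, a growth factor gene, at 9.83 CPM in BL6J WT 4 against 6.15 to 6.30 CPM (0.957). In BL6J KO 2, Ucp3, an uncoupling protein gene, was at 55.6 CPM against 18.5 to 20.2 CPM (0.955), Cyb5r2 at 6.79 CPM against 13 to 13.4 CPM (0.941) and Kif5a at 8.49 CPM against 11.8 to 12.3 CPM (0.877). Gapdh-ps15 was at 3.31 CPM in BL6J KO 1 against 1.03 to 1.27 CPM (0.893). In AJ-F1 WT, Nppa was at 333 CPM in library 2 against 83.1 to 110 CPM (0.891). Scn4b was at 85.0 CPM in library 4 against 53.0 to 57.6 CPM (0.857), Kcne1 at 18.4 CPM in library 1 against 30.8 to 33.3 CPM (0.836), and Hyal1 at 14.1 CPM in library 3 against 8.02 to 8.66 CPM (0.895). Total counts stood apart for the shallowest BL6J KO library (0.951) and the deepest AJ-F1 WT library (0.857).

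AJ-F1 WT 3 deviated most from its group. Its deviation followed transcript GC content with a rho of 0.732 across genes, so that base composition in library preparation or RNA quality is a candidate explanation. Whether RNA of a female animal was present was not decided. Y genes lay lower in AJ-F1 WT 3 (mean log2 deviation -2.02). Their X-linked partners lay lower there as well (-1.37), where added female RNA would have raised them. Yet the 3044 genes of lowest GC content also lay lower in that library (median -1.03). The deviations of the X-linked partners were not corrected for this trend, which could hide a rise. The GC trend was argued against as the source of the AJ-F1 calls, since 3908 genes were called with it removed, 2918 of them also without the correction. Haemoglobin reads were 0.127% of counts in that library and 0.248% in BL6J WT 4, which decided nothing about blood. No biological explanation for a single library was tested.

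Nppa rose in CAST-F1 KO and did not pass the test in AJ-F1 KO. That rested on AJ-F1 WT 2, without which Nppa passed in AJ-F1 KO as well (1.45, adjusted p = 0.025) and the difference was 3.91 (adjusted p = 0.0453). Atrial tissue in the CAST-F1 KO libraries was argued against: the 4 atrial markers chosen for this test (Sln, Myl7, Myl4 and Mybphl) had a median log2 change of 1.75 with none of them called, and Myl7, an atrial myosin gene, reached 14.2 CPM where Nppa stood at 1897 CPM. Of the fixed list of 10 atrium markers, 1 rose and 1 fell in CAST-F1 (1 and 2 adjusted over the list alone), with a median of 1.00. The library AJ-F1 WT 3 was argued against as the source, since the difference was 4.88 without it, although its adjusted p then passed 0.05. A response that is smaller in AJ-F1 for all genes was argued against, because AJ-F1 changes had a slope of 0.827 on CAST-F1 changes over 4399 genes and the ratio for Nppa was 0.136. A difference between the genetic backgrounds stays open as an untested biological explanation.

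Taz reads made up 13.3% of the WT level in BL6J KO, against 4.54% and 4.37% in the other backgrounds, a difference that did not pass the test. Reads of the overlapping gene Dnase1l1 were argued against, as that gene was at 7.16 CPM in BL6J KO and 7.50 and 8.73 CPM in AJ-F1 KO and CAST-F1 KO. WT RNA mixed into the BL6J KO libraries was argued against, since 15 genes, among them Clcn1 at 4.09% and Aqp4 at 6.01% of WT, lay at a smaller percent than Taz. Scaling was argued against, because the gap to the other backgrounds was at least 1.58 on the log2 scale under 3 scalings. Expression left from the targeted allele that differs between backgrounds could be the source and was not tested.

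Other splits of the same libraries were fitted to ask whether chance can be excluded. Chance was excluded for BL6J (2756 genes; 1 of 35 splits as large; highest other 168). It was excluded for both comparisons of controls (402 genes, 1 of 35, highest other 1, and 707 genes, 1 of 35, highest other 97). It was excluded for the average (5912 genes, 1 of 100, highest other 3119) and for the genes shared by all backgrounds (1327, 1 of 100, highest other 0). For the number of lists called on average (16), the share of splits as large (4 of 100) met the criterion set beforehand. Yet the highest other split gave 19 lists and the median of the other splits was 9 lists. This count excludes chance for no single list and for no list call within a background. Chance was not excluded for AJ-F1 (3521 genes, 2 of 35), where AJ-F1 WT 1, 3 and 4 against WT 2 and the KO libraries gave 4102 genes. That split kept all KO libraries on the same side with a single WT library added, so the KO effect entered it. It does not measure chance alone, and the splits leave the question undecided for AJ-F1. For CAST-F1 the 10 splits are too few (2498 genes; highest other 0). For the differences between backgrounds the splits exchanged KO and WT libraries within each background, so that the KO effect itself entered the difference, and they decide nothing about chance. Their values were 1 gene for AJ-F1 against BL6J (6 of 100 as large, highest other 633), 4 for CAST-F1 against BL6J (5 of 100, highest other 3627) and 11 for CAST-F1 against AJ-F1 (5 of 100, highest other 1922). Splits that call many times the real count point to a structure of the samples, here the exchanged genotypes.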

How the results depend on the processing

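GC correction, leaving out both AJ-F1 WT 3 and BL6J KO 2, and pooling BL6J with CAST-F1 were added after the data were seen; removing mitochondrially encoded genes was not run, as the table holds 0 of them. Of 4454 called values of named genes under other settings 4244 stayed called and 210 were lost, and of 8607 with a library left out 8170 stayed called and 437 were lost; 0 turned direction. The second total includes libraries outside the contrast, such as BL6J WT 1 for CAST-F1, without which 123 of 123 stayed. Leaving out a library of the same background lost 3 of 135 (AJ-F1 WT 2) to 17 of 135 (AJ-F1 KO 3). For CAST-F1 against AJ-F1, 0 of 9 stayed without AJ-F1 KO 1. Many of these genes were also chosen for their large changes in the main fit. The cause was not tested unless stated. With limma-voom and sample weights, BL6J gave 4247 genes, CAST-F1 4939, the differences AJ-F1 against BL6J, CAST-F1 against BL6J and CAST-F1 against AJ-F1 14, 72 and 133, and the controls of AJ-F1 and CAST-F1 217 and 2248. The DESeq2 Wald test gave 72, 27 and 86 for the differences and 707 for the AJ-F1 controls. A fold change of at least 1.2, a stricter hypothesis, gave 1829 in BL6J, 3550 on average, 0, 1 and 0 for the differences and 129 and 355 for the controls. Each background fitted alone gave 1323 in AJ-F1, 4100 in CAST-F1 and 832 shared. The fit to all libraries, which shares the estimate of the spread per gene between backgrounds, gave 3521 in AJ-F1 and 2498 in CAST-F1. With its own spread AJ-F1 thus had fewer calls and CAST-F1 more. Of the called values of named genes, 32 of 135 in AJ-F1 and 2 of 122 in CAST-F1 were lost in this way. With the GC correction the differences were 20, 7 and 38 and the CAST-F1 controls 1066; with both libraries left out they were 42, 9 and 26 and 1225. Upper-quartile factors gave 5 for AJ-F1 against BL6J, no filter 5 there and 5 for CAST-F1 against AJ-F1, DESeq2 size factors 2 for CAST-F1 against BL6J, and at least 1 CPM in 3 samples 2 there and 7 for CAST-F1 against AJ-F1. BL6J and CAST-F1 pooled against AJ-F1 gave 0 genes with edgeR in both ways of pooling, with 1582 and 1223 at an unadjusted p under 0.05, where the deposited DESeq2 calls number 23. With an estimated correlation 3, 3 and 3 lists were called within backgrounds, 2 on average and 0, 0 and 0 for the differences; fry called 2, 0 and 1 of the differences.

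The replicate block gave 2172 genes in AJ-F1 and 2, 0 and 1 for the differences, and turned the uncalled change of Col1a1, CAST-F1, to 0.0813. Paired by number, KO and WT libraries correlated by -0.18 to 0.0815 in BL6J, -0.229 to 0.0718 in AJ-F1 and -0.053 to 0.0727 in CAST-F1, with 0, 1 and 1 samples closest to their own number. The check thus gave no sign that the numbers pair the samples. With so few pairs it cannot exclude pairing.

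With each library left out in turn, counts ran from 2155 to 3504 in BL6J, 2135 (without AJ-F1 KO 3) to 4580 in AJ-F1, 1810 to 3288 in CAST-F1, 5422 to 6371 on average and 1093 to 1696 shared. AJ-F1 against BL6J ran from 0 to 57 (without AJ-F1 WT 2), with 0 without each AJ-F1 KO library, AJ-F1 WT 4, BL6J WT 2, 3 or 4, BL6J KO 1 or 3, each CAST-F1 WT library, or CAST-F1 KO 2 or 3. It was 3 without AJ-F1 WT 1 or BL6J KO 4, 5 without BL6J WT 1 and 7 without AJ-F1 WT 3 or BL6J KO 2. CAST-F1 against BL6J ran from 0 (without BL6J WT 1, CAST-F1 WT 1 or CAST-F1 WT 3) to 6 (without AJ-F1 WT 3). It was 2 without AJ-F1 KO 1 or 3 or BL6J WT 3 or 4, and 1 without AJ-F1 KO 2, AJ-F1 WT 4, BL6J WT 2, BL6J KO 2, 3 or 4, CAST-F1 WT 2 or any CAST-F1 KO library. CAST-F1 against AJ-F1 ran from 0 (without any AJ-F1 KO or CAST-F1 KO library, CAST-F1 WT 1 or CAST-F1 WT 3) to 14, with 2 without CAST-F1 WT 2 and 4 without BL6J WT 4 or KO 4. AJ-F1 controls ran from 117 (without BL6J WT 2) to 2065 (without AJ-F1 WT 2), with 245, 208 and 185 without BL6J WT 1, 3 and 4, and 257 and 169 without AJ-F1 WT 3 and 4. CAST-F1 controls ran from 305 (without CAST-F1 WT 1) to 1122 (without AJ-F1 WT 3), with 421, 405, 440 and 468 without CAST-F1 WT 2 and 3 and BL6J WT 2 and 4. Taz ran from -2.92 to -2.86 in BL6J, -4.90 to -4.21 in AJ-F1 and -4.77 to -4.20 in CAST-F1. Lists called ran from 10 to 14, 15 to 16 and 9 to 17 within backgrounds, 16 to 17 on average, and 10 to 15, 2 (without BL6J WT 3) to 6 and 9 to 14 for the differences. Lists lost were BL6J protein quality control without BL6J KO 3 or 4 (up to 0.0621). Also lost were immediate early genes without BL6J WT 2 or 4 (up to 0.0693) and endothelium without BL6J KO 4 (0.0944) in BL6J. In CAST-F1 protein quality control was lost without 6 libraries (up to 0.215), the tricarboxylic acid cycle without CAST-F1 WT 1 or 2 (up to 0.121), chaperones without CAST-F1 KO 3 (0.0764) and mesothelium without CAST-F1 WT 1 or KO 3 (up to 0.0815). By setting, fry lost immediate early genes in AJ-F1 (0.0516) and BL6J (0.13) and endothelium in BL6J (0.108). Protein quality control was lost with DESeq2 size factors in CAST-F1 (0.0516) and with the replicate block in BL6J (0.055) and CAST-F1 (0.0785). Uncalled changes turned sign for Col1a1, CAST-F1, with limma-voom (0.22), GC correction (0.10) and without CAST-F1 WT 3 (0.49), KO 2 (0.07) or KO 3 (0.00221), within a range of -0.26 to 0.49. Col3a1, CAST-F1, turned with limma-voom (0.13) and without WT 3 (0.33), within -0.36 to 0.33. Ctgf, AJ-F1, turned without KO 3, within -0.0646 to 0.55, and Postn, CAST-F1, without WT 1, within -0.00493 to 0.53.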

Other observations

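The tests of the deposited comparisons were chosen after the results were seen. Pdk4, the kinase gene that restrains pyruvate oxidation, rose in AJ-F1 by 2.01 ± 0.49 on the log2 scale (adjusted p = 0.0049, edgeR quasi-likelihood test; lost with limma-voom and sample weights and with the replicate block, adjusted p up to 0.106) and did not pass in BL6J (0.96, adjusted p = 0.15) or CAST-F1 (1.25, adjusted p = 0.11, and 0.031 when fitted alone). The changes of Pdk4 did not differ past the threshold (AJ-F1 against BL6J 1.05 ± 0.66, adjusted p = 0.57; CAST-F1 against AJ-F1 -0.76 ± 0.72, adjusted p = 0.759). Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, rose by 2.89, 2.06 and 1.92 and Aldh1l2, a mitochondrial folate enzyme gene, by 3.32, 3.53 and 2.15 in BL6J, AJ-F1 and CAST-F1. Postn, the periostin gene of activated fibroblasts, rose in BL6J by 0.93 ± 0.30 (adjusted p = 0.026). That call was lost in 6 settings and libraries left out (adjusted p up to 0.0934). In the main fit Postn passed in neither of the other backgrounds. With the GC correction it passed in AJ-F1 as a fall (-0.755, adjusted p = 0.05, just under the threshold), against -0.55 in the main fit. Its change differed by -1.48 ± 0.45 in AJ-F1 against BL6J (adjusted p = 0.251). Ucp3 did not pass the edgeR test with all libraries, but passed in BL6J without BL6J KO 2 (-1.41, adjusted p = 0.005) or BL6J WT 1 and in CAST-F1 without CAST-F1 WT 3 (-1.48, adjusted p = 0.021) or BL6J KO 2, and in both with limma-voom and sample weights. DESeq2 called it in CAST-F1 (adjusted p = 0.037).

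The deposited calls of the authors number 3263 genes for AJ-F1 (1461 up and 1802 down), 4246 for BL6J and CAST-F1 together, 423 between the WT groups, 312 between the KO groups and 23 for the difference of the KO effect. DESeq2 run on the same counts gave the same numbers. Of the 23 genes, Slc1a4, Psca, Kcne1 and Hyal1 were among the 15 genes of the pairwise edgeR differences. The fourth position of the deposited summary code equals the pooled KO against WT call in all 14732 genes and the call between KO groups in 10491. The summary category for KO alone holds 4064 genes, where the call columns for the WT and KO groups give 239, and the category for both holds 182, where they give 73.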
